A study of Mus musculus with 36 samples.

How the data were processed

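Small RNA libraries of FACS-sorted cells from mouse small intestine (strain C57BL6/2J) were prepared, per the labels, with the TriLink CleanTag small RNA kit. The deposited table lists a signal for each miRNA or isomiR in each library. Here an isomiR is an entry whose name carries an offset from the annotated miRNA. The authors divided read counts by 1 factor per library, as the table's values show: every value above 0 is a whole multiple of 1 step per library, within 0.001 reads. The step is the value of 1 read, so the reads per library were recovered from it. Library totals differ, so the scale is a size factor and not a share of a common total. The smallest listed value is 10 to 12 reads, so the table lists nothing under 10 reads and an entry at 0 can hold up to 9 reads. The tool of the scaling, the aligner and the read counter are not given in the sources used here. The labels give genome build mm9, and positions here are from the RefSeq annotation of GRCm38.p6.

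The table holds 2670 entries, 638 without an offset and 2032 with one. It has columns for 31 of the 34 small RNA libraries. The Progenitor population has 3 libraries that match no column and is not analysed here. A further 3 columns match no library's labels and were not used in any step. The samples, the comparisons, the fixed lists of genes and miRNAs, and the rule for naming were set before the data were examined. The comparisons were set for 9 populations, and the 8 with values were used, so each was contrasted with the mean of the other 7.

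Entries reaching a value of 10 in at least 2 libraries were kept, which left 1057 entries, 394 of them without an offset. The model was limma with group means for the 8 populations, on log2 of the value plus 1, with a trend in the prior variance and no covariate. All groups share 1 estimate of the spread, because they hold 2 to 6 libraries. Each population was contrasted with the unweighted mean of the other 7 population means, and 8 pairs of populations were contrasted directly. Tests were two-sided with Benjamini-Hochberg adjustment over the 1057 entries. An entry was called at adjusted p under 0.05 and an absolute log2 fold change of at least 1. It counted as exclusive to a population when it was called higher in each of the 7 pairwise contrasts. Several entries are copies of 1 mature sequence from more than 1 locus and are not independent. The labels do not state that replicates are separate animals, so p-values measure the spread between samples. Lanes and label formats of the libraries differ between most populations, so population cannot be told apart from lane or run in most contrasts. Goblet, tuft and Paneth libraries 5 and 6 share 1 label format. Sample numbers are shared by the 3 Sox9 fractions, and the labels give samples of 1 number a common code whose meaning is not stated. Residuals of Sox9 High and Sox9 Low samples with the same number correlated at 0.135 to 0.371 in the 4 pairs, so these are taken as paired, and the planned model without the number as a block is kept beside the blocked one.

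Simulated libraries with the depths and the 10-read minimum of the real ones tested the model, with 200 entries changed in each comparison. Before a change, each entry had 1 mean for all populations. The spread beyond counting error was set by a negative binomial dispersion of 0.1, and the shares below depend on these settings. In entries simulated without a change, the model made false calls in 264 of 593 (44.5%) for goblet cells, 223 of 586 (38.1%) for tuft cells, 223 of 580 (38.5%) for Paneth against goblet cells and 118 of 578 (20.4%) for CD24Low cells. The share was 67 of 586 (11.4%) for Paneth, 41 of 578 (7.09%) for Sox9 High, 40 of 587 (6.81%) for Sox9 Negative, 12 of 578 (2.08%) for Lgr5 High and 12 of 585 (2.05%) for Sox9 Low cells. For Sox9 High against Sox9 Low it was 17 of 586 (2.90%). In libraries simulated with no change at all, false calls were 312 of 776 entries for goblet, 306 for tuft and at most 1 for each other population. In goblet cells the model found 35 of 100 simulated 2-fold and 79 of 100 simulated 4-fold changes. For CD24Low cells these counts were 67 and 100 of 100. Raising every value under 100 to 100, called the common floor here, lowered the false calls to at most 1 in each comparison. In the real data it left 473 entries to test. At that floor the model found 25 of 64 simulated 2-fold and 54 of 73 simulated 4-fold changes in goblet cells. The planned model is kept for the counts. Each count is given with the number also called at the common floor, and directions and names are drawn from entries called under both, except members of the fixed lists for which the value with the floor is given. The floor was chosen after the data were seen.

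Named miRNAs were chosen by a fixed rule. Among entries called in a comparison with a mean of at least 100 in the higher group, the rule takes up to 10 with the largest rise and 10 with the largest fall, entries without an offset first. Every library of the higher group must lie above the median of the other group. The rule also names up to 10 exclusive entries per population with a mean of at least 100, the 3 most abundant entries of each population, and members of the fixed lists as examples. For the cell types it names genes of the fixed lists that are called. Table names such as mmu-mir-194-1-5p are written miR-194-1-5p, and a value is the deposited normalised read count. Errors are standard deviations over libraries, and SE is the standard error of a log2 fold change.

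The fixed miRNA lists are the mir-200 family (8 tested), mir-192, mir-194 and mir-215 (8), endocrine and neural miRNAs (21), the mir-17 to mir-92 clusters (21), let-7 and mir-98 (19), mir-34 and mir-449 (6), mir-29 (4), mir-148 and mir-152 (6), miRNAs linked to stem cells (17), leukocyte (6), stromal and muscle (10), endothelial (2) and erythroid (1) miRNAs, and the Dlk1-Dio3 cluster (8). Members are entries without an offset. Other fixed lists hold 3 genes used for sorting, 15 genes of miRNA biogenesis and silencing, 38 pairs of a host gene and its miRNA, and markers of 12 kinds of cell. A host gene is one whose transcript carries the miRNA. The marker lists cover stem cells, cycling progenitors, enterocytes, goblet, Paneth, enteroendocrine and tuft cells, T cells, B or plasma cells, myeloid cells, stromal cells and endothelial cells.

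The 2 single-cell libraries are, per the labels, 10x Genomics Chromium libraries of intestinal cells from 12-month-old wild-type mice. The deposited matrices hold the count of UMI (unique molecules) per gene and barcode, without scaling. The authors' annotation names the cell type of each barcode they kept. No doublet caller was run here, and the sources used do not say how doublets were treated, so some annotated cells can be doublets. Paneth cells had the highest median UMI, 73555 and 67245 per cell, but the lowest median number of genes, 2574.5 and 3504. Counts were summed per library and type, and edgeR's quasi-likelihood test, with TMM scaling and a library term, compared each of the 8 types with the mean of the others over 11610 genes. TMM factors for Paneth cells were 0.170 and 0.408, because few genes hold most of their counts. Scaling by total counts instead shifts the median gene by -2.10 (log2) in Paneth cells, and by 0.67 in EEC, 0.57 in tuft cells, 0.37 in secretory progenitors, 0.32 in progenitors and 0.27 in ISC. On simulated counts for Paneth cells, the test found 40 of 100 2-fold and 99 of 100 4-fold changes, with 6 false calls among 10964 unchanged genes.

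The miRNA values were also rescaled to equal library totals. That shifted the median entry by 0.45 in Paneth, -0.50 in Sox9 Negative, 0.27 in Sox9 High, 0.13 in Sox9 Low and -0.11 in goblet cells. Among the pairs, it shifted Sox9 High against Negative by 0.64, Sox9 Low against Negative by 0.54, Paneth against goblet by 0.50, Paneth against tuft by 0.31, Lgr5 High against Sox9 Low by -0.19 and Lgr5 High against CD24Low by -0.12. Where these shifts change a direction or a split of calls, the rescaled number is given. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.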

Results

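Small RNA was sequenced from sorted populations of the mouse small-intestinal epithelium, to compare miRNA levels between its lineages. The populations with values were CD24Low, goblet, Lgr5 High, Paneth, Sox9 High, Sox9 Low, Sox9 Negative and tuft. Sox9, CD24 and Lgr5 are a transcription factor, a surface protein and a stem-cell receptor whose levels separate cells of the intestinal crypt. Paneth cells secrete antimicrobial peptides, goblet cells secrete mucus, and tuft cells are chemosensory. There were 4 libraries each of CD24Low, goblet, Sox9 High, Sox9 Low and Sox9 Negative cells, 6 of Paneth, 3 of tuft and 2 of Lgr5 High cells. Recovered reads per library were 13348905 to 30958439 in CD24Low, 16013732 and 24611108 in Lgr5 High, 2945821 to 9229136 in Sox9 High, 1744418 to 4922437 in Sox9 Low and 2241831 to 6474637 in Sox9 Negative cells. Paneth libraries held 2575073 to 3862826 reads, goblet libraries 689763 to 1636615 and tuft libraries 475678 to 720400. The deepest library therefore held 65.1 times the reads of the shallowest. The value that 10 reads give ran from 1.06 in a CD24Low library to 68.9 in a tuft library, so an entry listed at 0 in goblet or tuft cells can lie above values that CD24Low cells list. Between replicates, Pearson correlations of log2 values were 0.785 to 0.969. Their spread exceeded counting error in every pair of replicates, with chi-square per degree of freedom of at least 44.2.

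**Figure D1:**
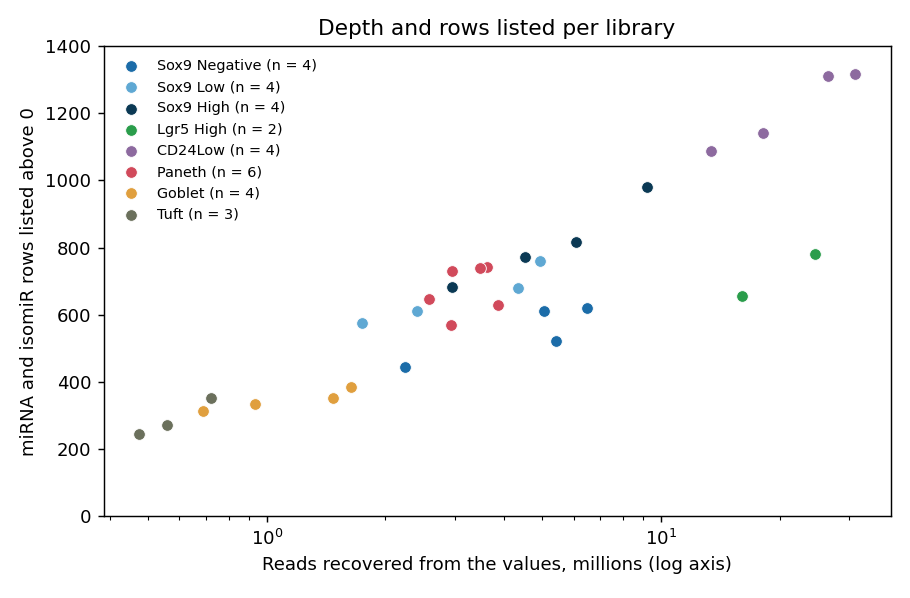
Reads recovered per library (in units of 1e6 reads, log axis) against the number of miRNA and isomiR entries listed above 0, with 1 point per library coloured by population. Tuft and goblet libraries, with 475678 to 1636615 reads, list 245 to 386 entries, and CD24Low libraries, with 13348905 to 30958439, list 1087 to 1315.

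The intestinal miRNAs miR-192-5p and miR-215-5p led the values of most populations. In Sox9 Negative cells miR-215-5p alone made up 46.0% of the library total, at 3003220 ± 910604 (SD, n = 4), followed by miR-194-1-5p at 690787 ± 200829 (10.8%) and miR-192-5p at 686803 ± 130852 (10.7%). Goblet cells had miR-215-5p at 1675800 ± 774596 (32.3%, n = 4), miR-192-5p at 806587 ± 52489 (16.4%) and let-7b-5p at 188824 ± 33302. In CD24Low cells the order was miR-215-5p at 1003290 ± 316501 (28.9%, n = 4), miR-192-5p at 534955 ± 6255 (15.6%) and let-7b-5p at 106455 ± 12801. Lgr5 High cells were led by miR-192-5p at 1136310 ± 41573 (30.3%, n = 2), let-7b-5p at 326660 ± 37127 and miR-215-5p at 222607 ± 33057. Paneth cells held miR-192-5p at 306801 ± 124149 (12.0%, n = 6), miR-148a-3p at 159565 ± 75353 (6.34%) and miR-215-5p at 155590 ± 61943. By mean value, the endocrine miRNA miR-375-3p came next to miR-192-5p in both Sox9-positive fractions. In Sox9 High cells miR-192-5p was at 324621 ± 13847 (11.0%, n = 4), miR-375-3p at 303242 ± 70192 (10.2%) and let-7b-5p at 223432 ± 81729. In Sox9 Low cells these 3 were at 419988 ± 139186 (13.1%, n = 4), 258588 ± 187258 (7.86%) and 253232 ± 56412. Tuft cells had miR-192-5p at 594507 ± 8764 (19.1%, n = 3), miR-182-5p at 298066 ± 20218 (9.54%) and miR-215-5p at 290261 ± 43993. In GRCm38.p6, miR-192-5p lies on chromosome 19 at 6264857 to 6264877 (+), and miR-215-5p and miR-194-1-5p lie together on chromosome 1, at 185313610 to 185313630 (+) and 185313325 to 185313346 (+).

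**Figure D2:**
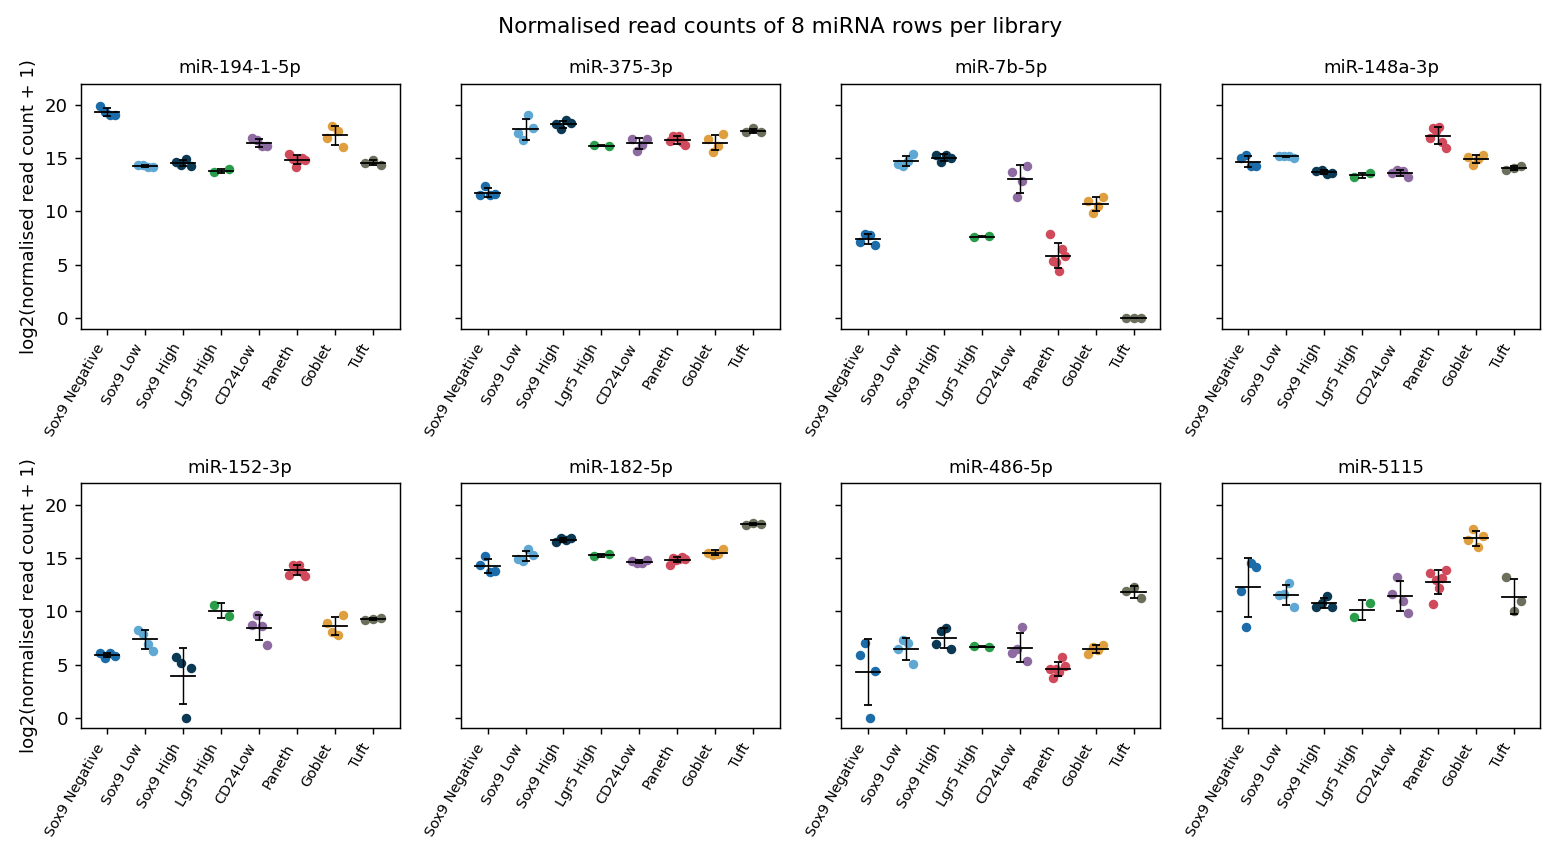
Log2 of the deposited value plus 1 for 8 miRNAs, with 1 point per library and the mean and SD of each population as bars. miR-194-1-5p is highest in Sox9 Negative, miR-7b-5p in Sox9 High and Sox9 Low, miR-152-3p in Paneth, miR-5115 in goblet and miR-182-5p and miR-486-5p in tuft libraries.

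Sox9 Negative cells carried more of most mir-192, mir-194 and mir-215 members and less of some endocrine and let-7 miRNAs, such as miR-375-3p and let-7e-5p, than the mean of the other populations. The contrast asks which miRNAs mark cells without Sox9. miR-194-1-5p was 4.25 higher in log2 than the mean of the other 7 populations (SE 0.23, adjusted p 2.2e-14), and goblet cells came next with a mean of 164725. miR-215-3p was 4.44 higher (SE 0.29, adjusted p 1.31e-12), at 55574 ± 15899 (n = 4). Of the mir-17 to mir-92 clusters, miR-106a-5p was 5.63 higher (SE 0.96, adjusted p 3.46e-05) at 227 ± 103. miR-375-3p (chromosome 1, 74900661 to 74900682, -) was 5.26 lower, a log2 fold change of -5.26 (SE 0.28, adjusted p 2.2e-14), at 3627 ± 1135 (n = 4). let-7e-5p changed by -4.26 (SE 0.28, adjusted p 1.29e-12), at 114 ± 46.1. miR-139-3p (chromosome 7, 101475418 to 101475439, +) was listed at 0 in all 4 libraries, and its log2 fold change with the common floor was -1.96. In the family of mir-192, mir-194 and mir-215, 7 of 8 members were higher, 7 adjusted over the list alone, 6 with the common floor and 5 after rescaling. Of the endocrine and neural miRNAs, 9 of 21 were lower, 10 adjusted over the list alone and 5 of 13 with the floor. let-7 and mir-98 members were lower in 6 of 19, 6 adjusted over the list alone and 6 of 15 with the floor. Members of the mir-17 to mir-92 clusters were higher in 7 of 21 and lower in 3, with 8 and 3 adjusted over the list alone, and 6 of 16 were higher with the floor, while rescaling gave 3 higher and 3 lower. In all, 196 entries were higher and 192 lower, of which 73 and 44 were also called with the common floor, and rescaling gave 123 higher and 247 lower and the edgeR count test on recovered reads 232 and 57.

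Sox9 High cells were rich in endocrine and neural miRNAs, such as miR-7b-5p and miR-184-3p, and poor in miR-152-3p. The question is which miRNAs mark the cells with most Sox9. miR-7b-5p (chromosome 17, 56243017 to 56243040, +) was 6.58 higher in log2 (SE 0.43, adjusted p 2.86e-12), at 34870 ± 7424 (n = 4). miR-184-3p (chromosome 9, 89802263 to 89802284, -) was 7.12 higher (SE 0.70, adjusted p 8.35e-09), at 911 ± 126. miR-672-5p was 5.15 higher (SE 0.38, adjusted p 3.24e-11), at 1205 ± 578, and miR-7a-2-3p, miR-132-3p and miR-127-3p were at 1168 ± 210, 549 ± 42.9 and 428 ± 115. Tuft cells held miR-672-5p at a like level, 1031 ± 549 (n = 3), so it is not particular to Sox9 High cells. miR-152-3p (chromosome 11, 96850439 to 96850459, +) had a log2 fold change of -5.18 (SE 0.60, adjusted p 1.7e-07), at 27.7 ± 21.7 with 1 library listed at 0. Endocrine and neural miRNAs were higher in 15 of 21, 15 adjusted over the list alone and 8 of 13 with the common floor. Of mir-148 and mir-152 members, 3 of 6 were lower, 4 adjusted over the list alone and 3 of 5 with the floor. All 8 tested members of the Dlk1-Dio3 cluster were higher, 8 adjusted over the list alone and 1 of 2 with the floor. Members of the mir-192, mir-194 and mir-215 family split into 1 higher and 4 lower, the same numbers adjusted over the list alone and with the floor. As planned, 279 entries were higher and 89 lower, and 37 and 40 of them were also called with the common floor.

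In Sox9 Low cells the leading miRNAs were again endocrine, and 8 of 17 miRNAs linked to stem cells were called higher. miR-184-3p reached its highest mean in this fraction, with a log2 fold change of 7.97 (SE 0.70, adjusted p 1.72e-09) and a value of 1982 ± 1786 (n = 4). miR-7b-5p was 6.17 higher (SE 0.43, adjusted p 4.05e-11), at 27799 ± 9822. miR-3096-5p, for which the RefSeq annotation carries no miRNA gene, was 3.71 higher, at 773 ± 181. Higher endocrine and neural miRNAs numbered 10 of 21, 10 adjusted over the list alone and 6 of 13 with the common floor. Of the miRNAs linked to stem cells, 8 were also called adjusted over the list alone and 5 of 11 with the floor. Leukocyte miRNAs were higher in 3 of 6, 3 adjusted over the list alone and 2 of 4 with the floor. The mir-192, mir-194 and mir-215 family held 1 member higher and 5 lower, the same numbers adjusted over the list alone and with the floor. Across the 1057 entries, 173 were higher and 98 lower, of which 42 and 31 were also called with the common floor.

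Sox9 High and Sox9 Low cells differed in 4 of 8 mir-200 members and miR-182-5p, which were higher in Sox9 High, and in miR-148a-3p, which was higher in Sox9 Low. The 3 fractions of Sox9 level ask how miRNAs follow the amount of Sox9. By their labels, Sox9 Low libraries are of lane L001, Sox9 Negative of L004 or L005, and Sox9 High of L002, except replicate 3 of L001. Fraction and sequencing lane therefore largely coincide and cannot be told apart in these pairs. miR-429-3p was 1.67 higher in Sox9 High (SE 0.27, adjusted p 9.25e-05), at 17436 ± 1742 against 5655 ± 1590 (n = 4 each). miR-200b-3p was 1.42 higher (SE 0.21, adjusted p 2.49e-05), at 36480 ± 5402 against 13917 ± 3672. miR-182-5p (chromosome 6, 30165962 to 30165986, -) was 1.51 higher (SE 0.24, adjusted p 0.000103), at 107155 ± 13171 against 39140 ± 14431. miR-148a-3p (chromosome 6, 51269829 to 51269850, -) changed by -1.45 (SE 0.31, adjusted p 0.00192), at 13476 ± 1585 against 36788 ± 1854. The mir-200 family was higher in 4 of 8 members, 4 adjusted over the list alone and 4 with the common floor. Endocrine and neural miRNAs were higher in 4 of 21, 6 adjusted over the list alone and 2 of 13 with the floor. The pair had 101 entries higher in Sox9 High and 29 lower, and 20 and 10 of them were also called with the common floor. Without Sox9 High replicate 4, the 130 calls became 81.

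Both Sox9-positive fractions exceeded Sox9 Negative cells in endocrine miRNAs such as miR-7b-5p and fell below them in miR-194-1-5p and miR-215-5p. miR-7b-5p was 7.64 higher in Sox9 High (SE 0.56, adjusted p 1.19e-11) and 7.28 higher in Sox9 Low than in Sox9 Negative cells. miR-194-1-5p changed by -4.81 in Sox9 High (SE 0.30, adjusted p 5.14e-13), at 24334 ± 4998, and by -5.06 in Sox9 Low (SE 0.30, adjusted p 3.59e-13), at 20083 ± 1299 (n = 4 each). miR-215-5p changed by -4.61 (SE 0.31, adjusted p 2.85e-12) and -4.27, at 120648 ± 19404 and 152019 ± 23403. miR-203-3p was at 1495 ± 256 in Sox9 High against 14435 ± 4215 in Sox9 Negative cells, a log2 fold change of -3.24 (SE 0.32). miR-184-3p, miR-672-5p, miR-7a-2-3p and miR-125a-5p were listed at 0 in every Sox9 Negative library. Endocrine and neural miRNAs were higher in 16 of 21 in Sox9 High and 11 of 21 in Sox9 Low, 16 and 11 adjusted over the list alone, and 8 and 7 of 13 with the common floor. let-7 and mir-98 members were higher in 6 of 19 in both pairs, 6 adjusted over the list alone and 6 of 15 with the floor. The family of mir-192, mir-194 and mir-215 was lower in 7 of 8 in Sox9 High and 6 of 8 in Sox9 Low, 7 and 6 adjusted over the list alone, and 6 and 5 with the floor. miRNAs linked to stem cells were higher in 10 of 17 and lower in 2 in Sox9 Low, the same numbers adjusted over the list alone, and 6 and 1 of 11 with the floor. Sox9 High against Negative gave 261 entries higher and 123 lower, with 56 and 69 also called at the floor, and 339 and 67 after rescaling. Sox9 Low against Negative gave 163 and 147, with 45 and 61 also called at the floor, and 243 and 87 after rescaling.

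Lgr5 High cells, the population sorted for the stem-cell receptor, had 7 of 19 let-7 and mir-98 members called higher and were low in miR-22-3p and miR-148b-3p. The contrast asks which miRNAs mark stem cells. miR-92a-1-5p was 5.34 higher in log2 (SE 0.73, adjusted p 2e-06), at 642 ± 288 (n = 2). miR-574-3p (chromosome 5, 64970364 to 64970385, +) was 2.91 higher (SE 0.35, adjusted p 6.95e-07), at 1276 ± 80.9, with Paneth cells at 955 ± 271 (n = 6). miR-218-1-5p was 3.41 higher (SE 0.42, adjusted p 6.95e-07), at 225 ± 9.42. miR-22-3p changed by -3.22 (SE 0.37, adjusted p 4.72e-07), at 904 ± 55.8. miR-148b-3p changed by -2.55 (SE 0.33, adjusted p 8.99e-07), at 302 ± 179. miR-194-1-5p changed by -2.05 (SE 0.31, adjusted p 9.18e-06), at 14728 ± 1937. The let-7 and mir-98 calls numbered 9 adjusted over the list alone, 5 of 15 with the common floor and 5 of 19 after rescaling. Endocrine and neural miRNAs were lower in 7 of 21 and higher in 1, the same numbers adjusted over the list alone, and lower in 3 of 13 with the floor. Of the miRNAs linked to stem cells 2 of 17 were higher, 2 adjusted over the list alone and 1 of 11 with the floor. Across all entries, 206 were higher and 87 lower, and 57 and 37 were also called with the common floor. Without Lgr5 High replicate 2, the 293 calls became 188, and the remaining library is then assumed to vary like the other groups.

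Against Sox9 Low cells, Lgr5 High cells held more miR-192-5p and miR-141-3p and far less of the endocrine miR-7b-5p. Sox9 Low and CD24Low are the other populations set against the stem-cell sort. miR-192-5p was 1.49 higher (SE 0.27, adjusted p 0.000122), and miR-141-3p was 1.53 higher (SE 0.37, adjusted p 0.00266), at 48199 ± 2651 against 18804 ± 10990. miR-7b-5p changed by -7.06 (SE 0.69, adjusted p 1.53e-08), at 199 ± 10.8. miR-184-3p and miR-132-3p were listed at 0 in both Lgr5 High libraries. Endocrine and neural miRNAs were lower in 9 of 21 and higher in 2, with 9 and 3 adjusted over the list alone, and lower in 6 of 13 with the common floor. Against CD24Low cells, of like depth, let-7d-3p was 2.32 higher (SE 0.46, adjusted p 0.000421) and let-7b-5p 1.62 higher (SE 0.28, adjusted p 7.21e-05). miR-181c-5p was 1.79 higher (SE 0.38, adjusted p 0.000926), at 7369 ± 630 against 2188 ± 596. let-7 and mir-98 members were higher in 6 of 19 and lower in 1, the same numbers adjusted over the list alone, and higher in 6 of 15 with the floor. The family of mir-192, mir-194 and mir-215 was lower in 5 of 8 and higher in 1, the same numbers adjusted over the list alone and with the floor. Stromal and muscle miRNAs were lower in 8 of 10, 8 adjusted over the list alone and 1 of 7 with the floor. Lgr5 High against Sox9 Low gave 155 entries higher and 111 lower, of which 42 and 34 were also called at the floor, while the edgeR count test gave 84 and 98. Lgr5 High against CD24Low gave 53 and 164, of which 22 and 26 were also called at the floor.

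CD24Low cells held more of the 10 tested stromal and muscle miRNAs than the mean of the other populations, together with more miR-7b-5p. Their depth was the highest of the 8 populations. miR-7b-5p was 4.28 higher in log2 (SE 0.43, adjusted p 5.11e-09), at 10918 ± 7644 (n = 4), still below both Sox9-positive fractions. miR-145-5p was at 118 ± 64.6 and listed at 0 in all 27 libraries of the other populations, and with the common floor it was 0.32 higher and no longer called. miR-143-3p (chromosome 18, 61649199 to 61649219, -) was 3.05 higher and 1.96 with the common floor, at 822 ± 449 against 762 ± 142 in Sox9 Negative cells. miR-199a-2-3p, at 160 ± 76.6, was likewise 0.60 higher and not called with the floor. miR-101a-3p changed by -2.65 (SE 0.30, adjusted p 7.08e-08), at 75.8 ± 24.6. miR-92a-1-3p changed by -2.15 (SE 0.44, adjusted p 0.000331), at 6905 ± 2683, and miR-423-3p by -1.81 (SE 0.31, adjusted p 4.33e-05). All 10 tested stromal and muscle miRNAs were higher, 10 adjusted over the list alone and 1 of 7 with the common floor, and 4 of the 10 were also called higher in Paneth, 2 in goblet, 2 in Sox9 High and 1 in Sox9 Negative cells. Leukocyte miRNAs were higher in 4 of 6, 4 adjusted over the list alone and 1 of 4 with the floor. Both tested endothelial miRNAs, miR-126-3p and miR-126-5p, were higher, 2 adjusted over the list alone, and the 1 that could be tested with the floor was not called. Endocrine and neural miRNAs were higher in 12 of 21 and lower in 1, with 14 and 1 adjusted over the list alone, and 3 and 1 of 13 with the floor. The 8 tested members of the Dlk1-Dio3 cluster were higher here too, 8 adjusted over the list alone, and the 2 tested with the floor were not called. Of the mir-192, mir-194 and mir-215 family, 4 of 8 were higher, 4 adjusted over the list alone and 3 with the floor. The contrast had 357 entries higher and 35 lower, and 51 and 16 of them were also called with the common floor. Without the floor, the model made false calls in 20.4% of unchanged simulated entries at this depth when 200 others were changed, and with no change at all limma called 0 of 776, although 247 passed at an unadjusted p under 0.05.

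Paneth cells were marked by miR-152-3p and miR-148a-3p, which share a seed, and by miR-34a-5p. The contrast asks which miRNAs mark this secretory lineage. miR-152-3p was 6.21 higher in log2 (SE 0.51, adjusted p 9.24e-11), at 15430 ± 5016 (n = 6), and Lgr5 High cells came next with a mean of 1134. miR-148a-3p was 2.89 higher. miR-34a-5p (chromosome 4, 150068473 to 150068494, +) was 4.93 higher (SE 0.68, adjusted p 1.63e-06), at 2338 ± 1387, with Sox9 Negative cells next at 565. miR-34c-5p was 4.27 higher (SE 0.63, adjusted p 4.59e-06), at 262 ± 86.2. miR-669c-5p (chromosome 2, 10509319 to 10509340, +) was 6.05 higher (SE 0.86, adjusted p 2.7e-06), at 1626 ± 490. Lgr5 High cells held it too, at 1188 ± 743 (n = 2), and the library values of the 2 populations overlapped. Of mir-148 and mir-152 members, 4 of 6 were higher, 4 adjusted over the list alone and 3 of 5 with the common floor. Of mir-34 and mir-449 members, 4 of 6 were higher, 4 adjusted over the list alone and 2 of 2 with the floor. Of mir-29 members, 3 of 4 were higher and 3 adjusted over the list alone, and the 1 tested with the floor was not called. The family of mir-192, mir-194 and mir-215 was lower in 3 of 8, 3 adjusted over the list alone and 3 with the floor, but rescaling gave 1 higher and 1 lower. As planned, 210 entries were higher and 115 lower, of which 25 and 31 were also called with the floor, and rescaling gave 328 and 107. Paneth libraries come in 2 label formats, and libraries 1 to 4 against 5 and 6 gave 92 entries higher and 2 lower, or 24 and 3 with the floor. With only libraries 5 and 6, Paneth calls fell to 131.

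Goblet cells were marked by miR-5115, miR-5105 and miR-5109 and by 4 of 8 members of the mir-192, mir-194 and mir-215 family. Their libraries were shallow, and most of their lower calls did not stay with the common floor. miR-5115 was 5.41 higher in log2 (SE 0.72, adjusted p 6.64e-07), at 130044 ± 62931 (n = 4), with Sox9 Negative cells next at 11313. miR-5109 was 3.39 higher (SE 0.35, adjusted p 1.14e-08), at 9431 ± 2721, and miR-5105 was 5.43 higher, at 6943 ± 4757. The RefSeq annotation carries no miRNA gene for these 3. miR-196a-2-5p was 6.34 higher (SE 1.01, adjusted p 1.04e-05), at 365 ± 276. miR-222-3p (chromosome X, 19146901 to 19146923, -) changed by -2.49 (SE 0.26, adjusted p 1.58e-08), at 59.5 ± 10.8. miR-181d-5p changed by -2.45 (SE 0.23, adjusted p 1.88e-09), at 440 ± 154. The family of mir-192, mir-194 and mir-215 was higher in 4 of 8, 4 adjusted over the list alone and 4 with the floor. Members of the mir-17 to mir-92 clusters were lower in 12 of 21, 12 adjusted over the list alone and 6 of 16 with the floor, 5 of them the same members. As planned, 99 entries were higher and 384 lower, of which 68 and 37 were also called with the floor, while the edgeR count test on recovered reads gave 136 higher and 41 lower. In unchanged simulated entries at this depth, the planned model made false calls in 44.5%.

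Tuft cells were marked by miR-182-5p, miR-486-5p and miR-139-3p, and lacked miR-7b-5p and miR-574-3p at their depth. Their libraries were the shallowest of the 8 populations. miR-182-5p was 2.99 higher in log2 (SE 0.21, adjusted p 3.44e-12), and Sox9 High cells came next. miR-486-5p was 5.72 higher (SE 0.80, adjusted p 1.55e-06), at 3724 ± 1311 (n = 3), against a mean of 205 in the next population, Sox9 High. miR-5119 was 8.42 higher (SE 1.18, adjusted p 1.54e-06), at 1662 ± 631. miR-139-3p was 4.16 higher (SE 0.40, adjusted p 2.47e-09), at 2477 ± 1359, and miR-27a-3p was 3.43 higher (SE 0.34, adjusted p 5.07e-09), at 950 ± 341. miR-7b-5p and miR-574-3p were listed at 0 in all 3 libraries, and their log2 fold changes with the common floor were -4.13 and -2.23. miR-486-5p, the 1 erythroid miRNA tested, was also called adjusted over the list alone and with the floor. In the mir-200 family 2 of 8 were higher and 1 lower, the same numbers adjusted over the list alone, and 2 were higher with the floor. Members of the mir-17 to mir-92 clusters were lower in 15 of 21, 16 adjusted over the list alone and 5 of 16 with the floor. let-7 and mir-98 members were lower in 6 of 19 and higher in 1, the same numbers adjusted over the list alone, and 3 and 1 of 15 with the floor. In all, 64 entries were higher and 423 lower, of which 45 and 79 were also called with the floor. The edgeR count test on recovered reads gave 98 higher and 150 lower.

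The 3 secretory populations differed in miR-34a-5p, higher in Paneth cells, miR-215-5p and miR-5115, higher in goblet cells, and miR-182-5p and miR-486-5p, higher in tuft cells. These pairs ask how secretory lineages differ from each other. Against goblet cells, Paneth cells held more miR-34a-5p (log2 fold change 7.63, SE 0.96, adjusted p 2.49e-07), and miR-34c-5p was listed at 0 in all goblet libraries. Goblet cells had miR-34a-5p at 46.3 ± 57.1, with 2 of 4 libraries listed at 0. The size of that fold therefore depends on the value of 1 added before the log. miR-215-5p changed by -3.41 (SE 0.28, adjusted p 9.6e-11) and miR-5115 by -4.13. Against tuft cells, Paneth cells held less miR-182-5p (-3.33, SE 0.24, adjusted p 5.41e-12), at 29932 ± 5042 (n = 6), and less miR-486-5p (-7.18, SE 0.93, adjusted p 3.66e-07), at 25.8 ± 13.2. Goblet cells also held less miR-182-5p than tuft cells (-2.68, SE 0.26, adjusted p 7.4e-09), at 47170 ± 9017 (n = 4). miR-183-5p was at 3624 ± 833 in goblet against 27753 ± 2364 in tuft cells (-2.96, SE 0.25, adjusted p 4.49e-10). The family of mir-192, mir-194 and mir-215 was higher in goblet than tuft cells in 7 of 8 members, 7 adjusted over the list alone and 6 with the common floor, and lower in Paneth than goblet cells in 5 of 8, 5 adjusted over the list alone and 5 with the floor, but rescaling gave 1 higher and 3 lower. The mir-148 and mir-152 members were all higher in Paneth than tuft cells, 6 adjusted over the list alone and 4 of 5 with the floor. The mir-200 family was lower in goblet than tuft cells in 4 of 8 and higher in 1, the same numbers adjusted over the list alone, and lower in 4 with the floor. let-7 and mir-98 members were higher in goblet than tuft cells in 5 of 19, 5 adjusted over the list alone and 5 of 15 with the floor, but rescaling gave 2 lower. Paneth against goblet gave 350 entries higher and 83 lower, of which 44 and 68 were also called at the floor. Paneth against tuft gave 420 and 66, with 77 and 47 also called, and goblet against tuft gave 149 and 57, with 83 and 38 also called and 116 and 77 after rescaling.

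**Figure D3:**
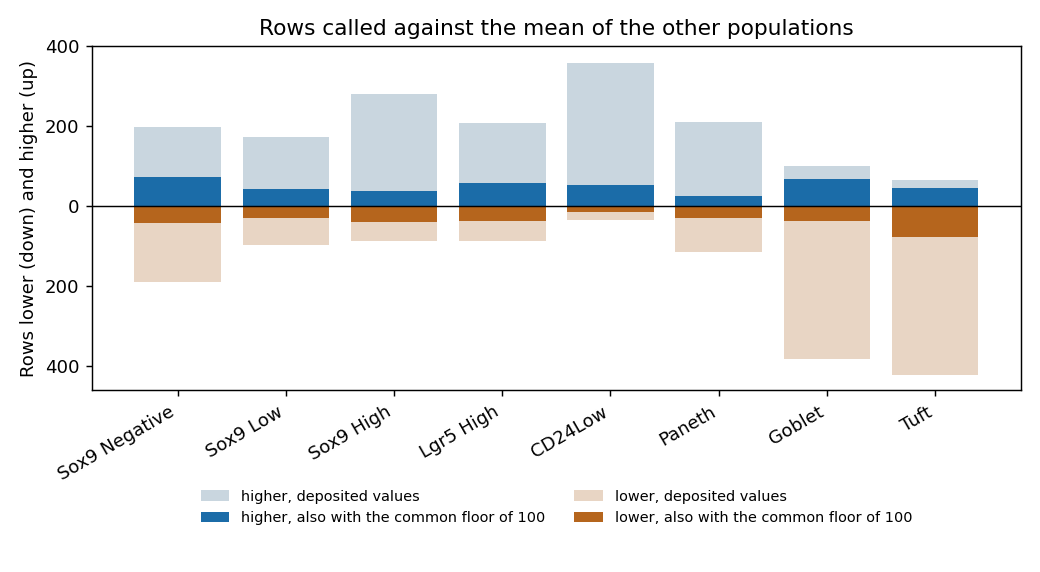
Number of entries called higher (upward) and lower (downward) in each population against the mean of the other 7, with the dark part also called with a common floor of 100. Goblet and tuft cells have 384 and 423 entries lower, of which 37 and 79 were also called at the floor.

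Each population but Sox9 High and Sox9 Low had entries that exceeded every other population both as planned and with the common floor. Goblet cells had 36 exclusive entries, and 32 were exclusive under both. These were miR-5109, miR-5115 and isomiRs of miR-5102, miR-5105, miR-5109 and miR-5115. Sox9 Negative cells had 30, of which 17 were exclusive under both, among them miR-194-1-5p, miR-215-3p, miR-31-5p at a mean of 82939, miR-378-3p at 166398 and miR-203-3p. Tuft cells had 13, of which 8 were exclusive under both, among them miR-182-5p, miR-486-5p, miR-27a-3p and miR-744-5p. With every library thinned at random to 475678 reads, miR-182-5p stayed exclusive, but miR-486-5p, miR-27a-3p and miR-744-5p did not. Paneth cells had 36, of which 4 were exclusive under both: miR-152-3p, miR-148a-3p, miR-101a-3p and miR-29abc-3p. Of these, miR-101a-3p alone was not exclusive after that thinning. Without Lgr5 High replicate 2 the Paneth number fell to 7. Lgr5 High cells had 13, of which 3 isomiRs of let-7c and let-7d were exclusive under both, and 22 without Lgr5 High replicate 1. CD24Low cells had 37, of which 2 isomiRs, of miR-215-5p and miR-375-3p, were exclusive under both. Sox9 High and Sox9 Low cells had 17 and 3 as planned and 2 and 5 with the floor, with no entry in common, and the Sox9 Low number ran from 1 to 6 when single libraries were left out. Rescaling took the numbers to 21 for goblet, 11 for Sox9 Negative and 6 for Sox9 Low cells.

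The single-cell libraries held intestinal cells of 8 annotated types, with enterocytes and progenitors the most frequent. Library 1 had 1144 annotated cells among 1209 barcodes and a median of 16547 UMI per annotated cell, and library 2 had 1470 among 7711 and a median of 24850.5 UMI. The annotated cells held 23947568 and 47974261 UMI. Exact (Clopper-Pearson) 95% intervals cover counting error only. Enterocytes made up 35.5% of library 1 (32.7 to 38.3) and 33.2% of library 2 (30.8 to 35.7), and progenitors 28.8% and 24.8%. Goblet cells made up 9.18% of library 1 (7.57 to 11.0) and 17.0% of library 2 (15.1 to 19.0). Paneth cells made up 7.34% and 5.03%, ISC (intestinal stem cells) 6.82% and 5.44%, secretory progenitors 7.17% and 9.93%, EEC (enteroendocrine cells) 3.06% in both, and tuft cells 2.10% and 1.56%. Both libraries are of 1 group, so no test between groups was possible. Each of the 7 epithelial marker lists summed highest in its own annotated type in both libraries. The enteroendocrine list reached 26119 and 45847 CPM (counts scaled to a common total) in EEC, the tuft list 6062 and 3895 in tuft cells, the Paneth list 441195 and 394392 in Paneth cells, the goblet list 172257 and 167455 in goblet cells and the enterocyte list 54513 and 24043 in enterocytes. The stem list reached 587 and 1154 CPM in ISC, and the cycling list 1352 and 1804 in progenitors.

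Genes used for sorting ranked cell types in ways that bear on the sorted populations. These comparisons ask which cell types hold sort genes, miRNA host genes and genes of the miRNA pathway. Sox9 mRNA was highest in tuft cells, at 261 CPM against 46.4 in the other types (log2 fold change 2.24, SE 0.18, adjusted p 1.6e-09, 2 libraries), and lowest in enterocytes (-3.30, SE 0.22). In Paneth cells Sox9 was called 1.74 higher with TMM scaling but was -0.42 with total counts. Cd24a was 3697 CPM in tuft cells against 277 in the others (3.68, SE 0.13, adjusted p 1.13e-16), 1.17 higher in EEC and -4.12 in enterocytes. In EEC Sox9 was -1.15 with TMM scaling and -0.41 with total counts, where it was not called, and it ran from -1.86 without single-cell replicate 1 to -0.42 without replicate 2. Lgr5 was 3.74 higher in ISC (SE 0.23, adjusted p 1.37e-10) and 1.73 higher in tuft cells (0.99 without replicate 1 and 1.36 without replicate 2). In Paneth cells Lgr5 was 3.98 and Cd24a 3.05 higher with TMM scaling, and 1.93 and 0.92 with total counts, where Lgr5 in ISC was 4.03. Copz2, the host gene of mir-152, was called higher in Paneth cells (adjusted p 1.95e-16), at 31.9 and 36.1 CPM in the 2 libraries, and in goblet cells, at 14.7 and 11.4 CPM, while EEC, enterocytes and tuft cells held no UMI of it. Vwa5b2, the host of mir-1224, was called higher in EEC (adjusted p 3.91e-15), at 140 against 0.221 CPM. Pde2a, the host of mir-139, was called higher in tuft cells (adjusted p 3.76e-10), at 88.6 against 14.6 CPM, and in goblet cells. Its fitted values were also higher in secretory progenitors and EEC, where it was called with total counts. With types at 0 UMI, fitted folds of these 3 host genes depend on the prior count and are not given. Mcm7, the host of the mir-106b cluster, was 1.88 higher in ISC and 1.44 in progenitors, and -2.58 in enterocytes. Of 13 tested genes of miRNA biogenesis and silencing, Dgcr8 was lower in goblet cells (-1.15, SE 0.22, adjusted p 0.000183), Xpo5 was 1.10 higher in progenitors and -1.28 in enterocytes, and Ago4 was -1.24 in progenitors. Some of these calls depended on the model: Ago4 was not called with DESeq2 (-1.39), without the library term (-1.25) or with total counts (-0.95). Xpo5 in progenitors was not called with DESeq2 size factors in edgeR (0.98) or without the library term (1.01), nor Xpo5 in enterocytes without the library term (-1.27). Without replicate 1 and without replicate 2, Xpo5 in enterocytes was -0.98 and -0.55, and Ago4 in progenitors -0.81 and -0.61. Values from 1 single-cell library are differences of log2 CPM with a prior count. Of the lists' 56 genes 40 were tested, and they gave 31 higher and 24 lower calls over the 8 types. The calls per list and type adjusted over the list alone were the same in number as those over all genes, for sort, pathway and host genes alike.

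**Figure D4:**
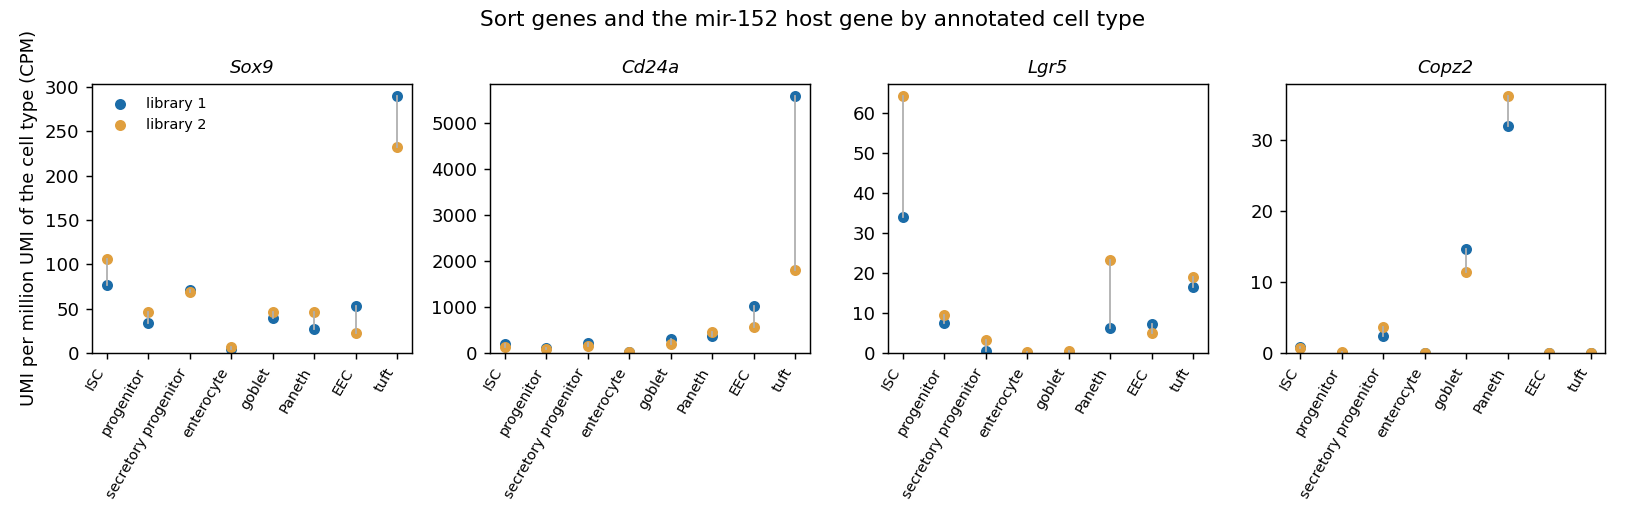
CPM (counts scaled to a common total) of Sox9, Cd24a, Lgr5 and Copz2 in each annotated cell type, with 2 dots per type for the 2 single-cell libraries. Sox9 and Cd24a are highest in tuft cells, Lgr5 in ISC and Copz2 in Paneth cells.

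Host genes and their miRNAs were ranked across 6 matched types, to ask whether sorted populations and droplet cell types order them alike. Paneth, goblet and tuft populations were matched by name, Lgr5 High with ISC, Sox9 High with EEC and Sox9 Negative with enterocytes. Over 21 of 38 pairs with values on both sides, the median Spearman rho was 0.0286, and a two-sided permutation test with 100000 reassignments of hosts to miRNAs gave p 0.434. This rho is across 6 types within each pair, and pairs are not independent replicates. Of the 21 pairs, 12 had a rho above 0. With single-cell library 2 alone the median was 0.2 and the permutation p 0.0366, and with library 1 alone it was -0.0857 with p 1.0.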

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

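Tests chosen only after their results were seen are those of the RefSeq annotation and of depth for the goblet miRNAs, of depth for all calls in goblet, tuft and CD24Low cells, of depth for stromal and muscle miRNAs taken alone, the comparison of a shared run with the goblet excess, thinning of the unannotated barcodes, and the split by list of the test for other cells in CD24Low.

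In 6 of 113 groups of values screened, 1 library lay far from the others of its population, and chance gives about 1 in 20. miR-375-3p in Sox9 Negative cells was 5323 in replicate 2 and 2964 to 3190 in the other 3 libraries. miR-106a-5p was 381 in Sox9 Negative replicate 1 against 159 to 187, and miR-20b-5p was 971 in the same library against 467 to 511. miR-1224-5p was 5410 in Sox9 Low replicate 3 against 502 to 613. The labels of sample 3 of all 3 Sox9 fractions carry the letters HFD where the other samples read chow, and no diet is given as a characteristic. miR-155-5p was 10194 in CD24Low replicate 2 against 73.1 to 205, and without that library its log2 fold change of 4.57 became 3.01 and was no longer called. miR-196a-2-5p was 775 in goblet replicate 4 against 174 to 276. No technical or biological explanation was tested for these values.

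Barcodes without an annotation in the single-cell libraries, which no comparison uses, held a UMI of Cd3g and Ptprc more often than annotated cells. In library 1, 23.1% of 65 such barcodes had a UMI of Cd3g and 27.7% one of Ptprc, against 6.99% and 3.50% of the annotated cells. In library 2 the shares were 25.3% and 25.2% of 6241 barcodes, against 5.71% and 3.74% of the annotated cells. Median depth was lower in the unannotated barcodes, at 11041 and 1738 UMI against 16547 and 24850.5. With each barcode thinned to 1000 UMI, which left out 1899 unannotated barcodes of library 2, the shares were 12.2% and 4.78% in library 1, against 0.476% and 0.215%, and 32.4% and 23.2% in library 2, against 0.732% and 0.250%. Of 18 listed T cell, B or plasma cell and myeloid genes, 13 in each library were in a higher share of unannotated barcodes, and 17 in each after thinning. The exceptions after thinning were C1qb in library 1 and Cd74 in library 2. By CPM 17 and 18 of the 18 were higher. The median mitochondrial share of unannotated barcodes was 15.6% and 70.2%, while annotated cells reached at most 14.5% and 15.0%.

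Most entries exclusive to goblet cells are miR-5109, miR-5115 and isomiRs of miR-5105, miR-5109 and miR-5115. For the 36 exclusive entries, unequal depth with the 10-read minimum is argued against, since 88.9% (32 entries) were also exclusive with the common floor. After thinning every library to 475678 reads, the smallest of their 7 pairwise log2 folds was at least 1 in each of the 36, with a median of 2.89 (quartiles 2.45 to 3.75) against 2.84 (2.48 to 3.30) before, but 14 were called exclusive, because adjusted p of the others missed the threshold. Goblet libraries share a label format with Paneth libraries 5 and 6 and with the tuft libraries, so a shared library run was examined. These entries were higher in Paneth libraries 5 and 6 than in 1 to 4 by a median of 0.349 in log2 (quartiles -0.155 to 0.675). Goblet libraries exceeded Paneth 1 to 4 by a median of 3.51 (quartiles 3.16 to 3.99). Paneth libraries 5 and 6 thus did not share most of this excess. However, the entries were picked as higher in goblet than in Paneth and tuft cells, so low values there are partly built in. The comparison therefore does not decide whether a run contributed. RefSeq carries no miRNA gene for 88.9% of the 36, against 7.95% of all entries tested, so fragments of other RNA that the miRNA names do not describe may make up these values. Those 88.9% are all entries of miR-5102, miR-5105, miR-5109 or miR-5115, which differ mostly by offset. The shares of the 36, also those for depth, thus hold fewer independent measurements than entries. Entries of the same names also lie behind the 7.95%. A difference in goblet cells themselves stays open, and reads that would tell the RNA of origin are not in the deposited table.

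For stromal, muscle, endothelial and leukocyte miRNAs, higher in the deep CD24Low libraries, depth cannot be told apart from a real difference, because 50% of the members called higher (8 of 16) were called after thinning, and others could no longer be tested. For stromal and muscle miRNAs alone depth is argued against, since 70.0% (7 of 10) stayed called, 7 of the 7 that could still be tested. In the Lgr5 High libraries of like depth 8 of 10 were lower, 7 of 7 after thinning. Members such as miR-199a-2-3p and miR-1a-2-3p have copies of the same mature sequence at other loci, so these counts hold fewer independent measurements than members. With the common floor 1 of 7 was called, and the other 6 were 0.32 to 0.60 higher, because their means of 118 to 160 lie close to that floor. Cells of those types in the CD24Low sort cannot be told apart from a difference in the CD24Low cells: of the members that could be tested after thinning 61.5% (8 of 13) were called higher, but these were 7 of 7 stromal and muscle and 1 of 5 leukocyte miRNAs, and the 1 endothelial miRNA was not called. miR-143-3p, the most abundant stromal member at 822 in CD24Low cells, reached 762 in Sox9 Negative cells too, and the labels say that epithelial populations were sorted without giving the gates.

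Many entries were lower in goblet and tuft cells, whose libraries are the shallowest, and higher in CD24Low cells, whose libraries are among the deepest. Of 1164 such calls, 25.3% (295) stayed after thinning to equal reads, but 738 could be tested then. Of those tested, 72 of 248 stayed for calls lower in goblet, 130 of 317 for lower in tuft and 93 of 173 for higher in CD24Low cells, and other populations lost calls too, with 29 of 73 staying for lower in Sox9 Low and 33 of 75 for lower in Sox9 High cells. In simulated libraries without any change, limma falsely called 311 of 776 entries lower in goblet and 306 in tuft cells but 0 higher or lower in CD24Low cells, where 247 passed at an unadjusted p under 0.05. Unequal depth with the 10-read minimum can therefore by itself give many calls lower in goblet and tuft cells. Of the 384 and 423 such calls, 37 and 79 were also called with the common floor. In the simulated libraries without any change, 0 entries were called with the common floor in goblet, tuft or CD24Low cells. This argues against depth as the source of calls also made with the floor, taken as a set. For any other single call, also those higher in CD24Low cells, depth cannot be told apart from a difference between these populations. The stromal and muscle miRNAs above, taken as a set, are the exception.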

How the results depend on the processing

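The common floor of 100, thinning to equal reads, the edgeR count test on recovered reads, entries without an offset only, leaving out the tuft libraries, total counts for the single cells, and each single-cell library alone were chosen after seeing the data. Alternatives set for the Progenitor population were not run, since it has no values. For counts of calls, moved means outside 1.5 times the main count.

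Rescaling to equal totals moved 3 of 24 counts, to 21 for exclusive entries of goblet, 6 of Sox9 Low and 11 of Sox9 Negative cells. A pseudocount of 10 moved 5, to 231 for CD24Low and 199 for Paneth calls, and to 20, 11 and 6 for exclusive entries of Lgr5 High, Sox9 High and Sox9 Low cells. No filter moved 4, to 133, 75 and 26 for exclusive entries of CD24Low, Lgr5 High and Sox9 High cells and 389 for Lgr5 High against CD24Low. Fitting only the 2 groups compared moved 3 of 8, to 113 for goblet against tuft, 157 for Lgr5 High against Sox9 Low and 69 for Sox9 High against Low, with fewer samples behind each spread. The replicate block, in the labels' sample numbers, gave 142, 395 and 319 calls for the 3 Sox9 pairs, and leaving out sample number 3 moved none of them either. Of the named miRNAs in these pairs, the block ended the call of miR-1839-5p in Sox9 High against Low, at 1.30, and of no other. Against Sox9 Negative samples the residuals of 6 of 8 same-number pairs correlated above 0.1 (range -0.267 to 0.296), and over the 3 fractions 7 of 12 samples correlated best with their own number. Only Paneth libraries 1 to 4 moved none of 4 counts, and only libraries 5 and 6 moved all 4, to 131 Paneth calls, 9 exclusive entries, 236 against goblet and 301 against tuft cells, with fewer libraries. For the other moved counts of this paragraph the cause was not tested.

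The common floor, which leaves 473 entries, moved 19 counts. Calls became 81 for CD24Low, 122 for goblet, 117 for Lgr5 High, 71 for Paneth, 96 for Sox9 High, 91 for Sox9 Low, 130 for Sox9 Negative and 129 for tuft cells. Pairs became 90 for Lgr5 High against CD24Low, 121 for Lgr5 High against Sox9 Low, 136 for Paneth against goblet, 132 for Paneth against tuft, 50 for Sox9 High against Low, 157 for Sox9 High against Negative and 138 for Sox9 Low against Negative. Exclusive entries became 5 for CD24Low, 9 for Paneth, 2 for Sox9 High and 5 for Sox9 Low cells. Thinning, which leaves 583 entries, moved 21 counts. Calls became 125 for CD24Low, 172 for goblet, 128 for Lgr5 High, 171 for Paneth, 155 for Sox9 High, 116 for Sox9 Low, 187 for Sox9 Negative and 196 for tuft cells. Pairs became 80 for Lgr5 High against CD24Low, 112 for Lgr5 High against Sox9 Low, 174 for Paneth against goblet, 232 for Paneth against tuft, 51 for Sox9 High against Low, 195 for Sox9 High against Negative and 156 for Sox9 Low against Negative. Exclusive entries became 6 for CD24Low, 19 for goblet, 6 for Lgr5 High, 17 for Paneth, 6 for Sox9 High and 15 for Sox9 Negative cells. Fewer entries were tested in both.

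With the 394 entries without an offset, 22 counts moved because fewer entries were tested. Calls became 123 for CD24Low, 164 for goblet, 98 for Lgr5 High, 152 for Paneth, 126 for Sox9 High, 106 for Sox9 Low, 159 for Sox9 Negative and 206 for tuft cells. Pairs became 95 for goblet against tuft, 116 for Lgr5 High against CD24Low, 104 for Lgr5 High against Sox9 Low, 168 for Paneth against goblet, 227 for Paneth against tuft, 57 for Sox9 High against Low, 150 for Sox9 High against Negative and 122 for Sox9 Low against Negative. Exclusive entries became 12 for CD24Low, 4 for goblet, 3 for Lgr5 High, 8 for Sox9 High, 14 for Sox9 Negative and 6 for tuft cells. The edgeR count test moved 10 counts, to 177 for goblet, 248 for tuft, 125 for Lgr5 High against CD24Low and 40 for Sox9 High against Low. Its exclusive entries were 4 for CD24Low, 8 for Paneth, 13 for Sox9 Negative and 4 for tuft cells, and 0 for Lgr5 High and 0 for Sox9 High cells, where 3 and 1 passed at an unadjusted p under 0.05 and limma gave 13 and 17. Leaving out the tuft libraries moved 2 exclusive counts, to 20 for Lgr5 High and 6 for Sox9 Low cells. The cause was not tested for the count test, and without tuft libraries there is 1 contrast fewer to pass.

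Leaving out 1 library at a time kept 548 of 560 results. Calls ran from 320 to 418 for CD24Low, 408 to 509 for goblet, 188 to 309 for Lgr5 High, 262 to 342 for Paneth, 301 to 391 for Sox9 High, 240 to 293 for Sox9 Low, 310 to 406 for Sox9 Negative and 410 to 515 for tuft cells. Exclusive entries ran from 33 to 42, 26 to 37, 10 to 22, 7 to 44, 12 to 18, 1 to 6, 23 to 34 and 9 to 14 in the same order. The pair of Sox9 High and Low ran from 81 to 126. Lgr5 High replicate 2 gave the lowest Lgr5 High and Paneth exclusive counts. The host-gene median rho ran from -0.0857 to 0.2.

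Total counts as the only scaling moved the single-cell calls from 55 to 91, and the other settings gave 44 to 59. Sox9 in Paneth cells became -0.42 with total counts, because the median gene shifts there. Copz2 in secretory progenitors ran from -0.19 without single-cell replicate 2 to 0.36 without replicate 1, where a difference of log2 CPM with a prior count stands in for a fitted fold, because several types hold no UMI of it. Of the named miRNAs in their comparisons, 269 of 285 kept their call after rescaling, 262 of 285 in the count test, 258 of 285 after thinning and 210 of 282 with the common floor. Reversed with the floor were miR-184-3p in CD24Low at -0.50, and miR-5119 and miR-1224-5p in goblet cells at -0.17 and -0.19, where the floor raises values of 0 in other libraries to 100. Over single libraries left out, 1607 of 1708 kept their call and 101 lost it. The 10-read minimum lies at higher values in goblet and tuft libraries than in the other populations, which limits their comparison with the deeper libraries.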

Other observations

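Tests chosen only after their results were seen are the counts over other splits of the libraries, also those that part all pairs, and the host-gene alternatives with TMM scaling, with the common floor and with each single-cell library alone.

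Other ways of dividing the same libraries into groups of the same sizes were refitted, with 100 drawn where there are more. Few or none of the other splits gave as many calls for any of the 20 results of groups of at least 3 libraries. The real splits also carry differences in depth, lane and label format, so these counts do not tell such differences from those between cells. With no change simulated at the real depths, false calls still numbered 312 of 776 for goblet and 306 for tuft cells. In 19 of them the real split alone gave as many calls, so the number of splits as large was 1, and for the exclusive entries of tuft cells it was 2 of 100. The real numbers and the highest of the other splits were 392 and 46 for CD24Low, 483 and 10 for goblet, 325 and 171 for Paneth, 368 and 83 for Sox9 High, 271 and 80 for Sox9 Low, 388 and 98 for Sox9 Negative and 487 and 39 for tuft cells. Exclusive entries gave 36 and 1 in goblet and 13 and 21 in tuft cells, and the highest other split gave 0 in the other 5 populations. For 35 splits they were 130 and 43 for Sox9 High against Low, 384 and 40 for Sox9 High against Negative, 310 and 48 for Sox9 Low against Negative and 206 and 146 for goblet against tuft cells. Paneth against goblet cells gave 433 and 315 over 100 splits, and Paneth against tuft cells 486 and 236 over 84. Lgr5 High has 2 libraries, so its results have no such count. For Sox9 High against Low, whose samples pair by number, 8 of the 35 splits part all 4 pairs, too few for a share under 0.05. The highest of the other 7 gave 10 calls against 130, or 17 against 142 with the number as a block, and the 27 that part fewer pairs gave up to 43. The pairs with Sox9 Negative share sample numbers too, with 8 splits each that part all numbers. Among those, the highest other split gave 11 against 384 for Sox9 High and 32 against 310 for Sox9 Low.

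Genes with a site for an abundant miRNA in their 3' UTR were compared with matched random lists of genes in the cell type matched with a population in which the miRNA is abundant, over 10807 genes and 10000 draws. Genes with a site for miR-194-5p were lower in enterocytes, with a median log2 fold of -0.178 over 455 genes at percentile 0.13 of the random medians (-0.131 to 0.0519), which is consistent with an effect of miR-194-5p on its targets there, if enterocytes hold it as Sox9 Negative cells do. miRNAs were not measured in the annotated types: Paneth and tuft cells were matched by name, while enterocytes with Sox9 Negative and EEC with Sox9 High cells are assumed matches, and Sox9 mRNA in EEC was -1.15, or -0.41 and not called with total counts, and ran from -1.86 to -0.42 when 1 single-cell library was left out. For 3 other miRNAs the median lay within the range of random lists, so an effect cannot be told apart from none. Genes with sites for miR-148a-3p in Paneth cells had a median of -0.0617 (521 genes, percentile 5.53), those for miR-375-3p in EEC -0.141 (50 genes, percentile 11.2), and those for miR-182-5p in tuft cells -0.0809 (613 genes, percentile 22.02). These 4 tests were set before their results were seen, and their percentiles are not adjusted for 4 tests. The cell types differ in many regulators besides the miRNA, and that is untested.

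Joint transcription of a host gene and its miRNA would give a positive correlation across the matched types. The permutation p of 0.434 does not decide it, because the alternatives ran from 0.0366 with single-cell library 2 alone to 1.0 with library 1 alone. TMM-scaled host values gave a median rho of 0.257 with p 0.117, the common floor gave 0.0857 with p 0.377, and leaving out the match of Sox9 High with EEC gave -0.0574 with p 0.707.

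Markers of cells outside the epithelium were low in the annotated cell types, apart from the myeloid list. The stromal list summed to at most 0.196 CPM and the endothelial list to at most 18.8 CPM in any type and library. The B or plasma cell list summed to at most 19.6 CPM and the T cell list to at most 143 CPM. The myeloid list, which holds Cd74 and Lyz2, summed to 2318 and 1695 CPM in enterocytes. Over all annotated cells Cd74 was at 1143 and 1111 CPM and Lyz2 at 13.9 and 7.30, so Cd74 made up most of this list's signal. Gzma, of the T cell list, reached 2426 and 2617 CPM in unannotated barcodes against 25.4 and 32.9 in annotated cells.

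Sox9 Negative libraries from 2 sequencing lanes differed in 13 entries, 7 higher and 6 lower.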
